A study of Homo sapiens with 10 samples.

How the data were processed

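Poly(A) RNA was measured in 10 libraries of human PGP1 induced pluripotent stem cells with 6 transcription factors under doxycycline control, 2 libraries from each of days 1, 2, 3, 4 and 6 of 0.5 µg/mL doxycycline in mTeSR Plus. Per the labels' protocols, RNA was taken up in TRIzol and purified with Direct-zol columns, and directional libraries were made with NEBNext Ultra II after poly(A) selection. Per the submitters' processing notes, reads were aligned with STAR 2.5.2b to GRCh38. The values used were the read counts per gene that the authors deposited, as integers without scaling. The counter, its strand setting and the annotation release are not given in the sources used here, so antisense reads may add to genes whose exons overlap on the other strand. Of 58302 gene identifiers, 58039 were found in GENCODE 29, which gave symbols and GRCh38 positions, and the other 263 held 0.014% of the counts. Libraries from day 0 are named in the series design and were not used here.

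Whether the libraries of a day could be a single library sequenced again was tested first, by a chi-square over genes with at least 20 reads in the pair. Chi-square per degree of freedom was 1.59 on day 1, 17.42 on day 2, 3.28 on day 3, 2.36 on day 4 and 3.42 on day 6, all above the limit of 1.1 set for summing a pair, so every library was kept as a replicate. Total counts per library were 18074714 to 21256957. At that depth 3 counts, the 95% upper bound for a gene without a read, are 0.141 to 0.166 CPM. Such bounds hold counting error only.

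Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low counts were filtered by day with edgeR's default rule, which kept 18385 genes, and libraries were scaled by TMM, with factors from 0.935 to 1.039. A model with the 5 days as groups was fitted to all 10 libraries, which left 5 residual degrees of freedom and a common biological coefficient of variation of 0.0735. Each pair of days was tested with edgeR's quasi-likelihood test, and p-values were adjusted over all genes by the Benjamini-Hochberg method. A gene was called higher or lower at adjusted p under 0.05 with at least a 2-fold change, "neither" otherwise. The comparisons were day 6 against day 1, each sampled day against the sampled day before it (day 6 against day 4 for the last), and a joint F test over days. A transient rise was a gene called higher than day 1 on day 2, 3 or 4 and called lower on day 6 than on that day, and a transient fall the reverse. SE values were taken as the log2 fold change divided by the square root of the F statistic, which can be too small where a day has few reads, so where the error from the number of reads alone was larger it is given as counting error beside the SE.

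The 37 gene lists were written before the files were opened and hold 873 genes, 23 of them in more than 1 list. They cover the induced factors, pluripotency, epithelial, mesenchymal, mesoderm, endothelial, hematopoietic transcription factor, leukocyte and myeloid, homeostatic and disease-associated microglia, complement, phagocyte oxidase, Toll-like, cytokine, interferon, MHC class II and class I, lysosome, granulocyte, mast cell, erythroid and megakaryocyte, lymphoid, neural, endoderm, trophoblast, adipocyte, cholesterol synthesis and efflux, glycolysis, oxidative phosphorylation, DNA replication, mitosis, p53, stress response, immediate early, ribosomal and mitochondrial mRNA genes. Each was tested between days 6 and 1 with limma 3.58.1 camera at a preset correlation of 0.01 between genes, against all other tested genes, with Benjamini-Hochberg adjustment over the lists. Beside it stand the members called over all genes and the members called with p-values adjusted over the list alone. Of 3 lists with a member at 0 counts on a day, 0 medians moved when that member was set to the 3-count bound. For members with 3 counts or fewer on a day, counts are given and no fold change.

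Genes were named by a rule set in advance. For day 6 against day 1 it takes the induced factors, up to 4 called members of each list with the largest change, and the 12 genes higher and 12 lower with the largest change among called genes of at least 20 CPM in the higher day whose libraries did not overlap between days. For each later comparison and for transient genes it takes 6 in each direction in the same way, and 13 markers of microglia, leukocytes and pluripotency are given in any case. XIST and Y-linked genes were left out, and some genes the rule names are not reported. The text prints part of the genes the rule names, largest change first, and says so where another gene was chosen after its values were seen.

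The code was tested on simulated counts drawn from the means and library sizes of the real genes. For day 6 against day 1 over 17801 genes, 15 of 17605 unchanged genes passed the adjusted p with edgeR, and of genes given a 1.5-fold change 60% passed it. The changed list, with every gene raised 4-fold, was called by camera and 0 of 20 unchanged lists were. Genes were drawn independently of each other, so this does not test camera where genes are correlated. Principal components were computed on log2 CPM of the tested genes. Alternatives set in advance were DESeq2 1.42.0, limma-voom, scaling by DESeq2's size factors (RLE) or by library totals, no filter or a minimum of 1 CPM in 2 libraries, a test against a 2-fold change (glmTreat), adjusted p alone, a fit on the compared days only, a replicate block, leaving out each library, and for lists an estimated correlation or limma's fry. Leaving out both day 2 libraries or both day 4 libraries was added after seeing the data. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.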

Results

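Human induced pluripotent stem cells of the PGP1 line carrying 6 transcription factors under doxycycline control were followed by bulk sequencing of poly(A) RNA. Doxycycline, the drug that switches the factors on, was given at 0.5 µg/mL, and the cells stayed in mTeSR Plus, a stem cell medium. The purpose of the time course was to follow the cells toward a state resembling microglia, the resident macrophages of the brain. The 10 libraries fell into 5 groups of 2, from days 1, 2, 3, 4 and 6. Day 0, which the series design also names, was not analysed here, so day 1 served as the reference and those cells had already had 1 day of the drug. Total counts were 18819421 and 19261258 on day 1, 19809660 and 18074714 on day 2, 19429425 and 20632869 on day 3, 20544203 and 20136911 on day 4 and 20286645 and 21256957 on day 6. Between 24727 and 27214 genes had a read in a library, and 18385 genes were tested. A gene without a read in a library could have been present at up to 0.141 to 0.166 CPM (counts scaled to the library's total), the level of 3 counts, and this floor covers counting error only. Nothing in the labels says that the 2 libraries of a day came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Values are means of normalised CPM with SD over n = 2 libraries, and fold changes are on the log2 scale with their standard error (SE).

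The libraries were ordered by day. On the first principal component, which held 69.2% of the variance, day 1 lay at -127 and -126, day 2 at -39.1 and -37.5, day 3 at 22.8 and 21.5, day 4 at 65.2 and 59.4, and day 6 at 81.2 and 79.6. Pearson's r across genes between the libraries of a day ran from 0.984 on day 2 to 0.992 on day 6, with genes not being independent replicates. The median absolute log2 difference between libraries was 0.163 on day 2 and 0.05 to 0.071 on the other days, so values of day 2 carry a larger error than the rest. The fit takes a single spread per gene for all days. SE values may therefore be too small for comparisons with day 2 and too large for the others. The share of counts from the mitochondrial chromosome was 3.39% to 4.52%, and the 10 most abundant genes took 4.3% to 5.33%.

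**Figure D1:**
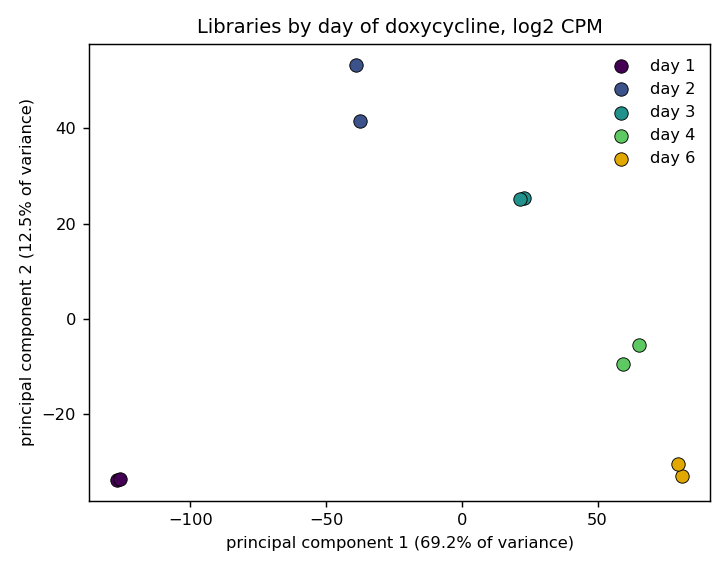
Principal components 1 (x axis, 69.2% of variance) and 2 (y axis, 12.5%) of log2 CPM, with each point a library and each colour a day. The days follow each other from left to right along component 1, from -127 on day 1 to 81.2 on day 6.

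The first question was whether the 6 factors were expressed throughout. SPI1, FLI1, MEF2C, IRF8, CEBPA and CEBPB were all abundant on day 1 and higher on day 2. FLI1 (ENSG00000151702, GRCh38 chromosome 11, 128686535 to 128813267) went from 1246 ± 3.61 CPM on day 1 to 3373 ± 29.3 on day 2 and 2957 ± 14.1 on day 6. MEF2C (ENSG00000081189, chromosome 5, 88717117 to 88904257) went from 733 to 2430 and then 1789 CPM, and IRF8 (ENSG00000140968, chromosome 16, 85898803 to 85922609) from 736 to 2445 and then 1709 CPM. SPI1 (ENSG00000066336, chromosome 11, 47354860 to 47378576) rose from 353 ± 2.24 to 987 ± 15.8 CPM between days 1 and 2 and stood at 887 ± 33.3 CPM on day 6. CEBPA (ENSG00000245848, chromosome 19, 33299934 to 33302564) rose from 95.0 to 229 CPM and CEBPB (ENSG00000172216, chromosome 20, 50190734 to 50192689) from 73.4 to 195 CPM. All 6 were called higher on day 2 than on day 1 (edgeR's quasi-likelihood test). Day 6 exceeded day 1 in 5 of the 6, from CEBPA (log2 fold change 1.03, SE 0.07, adjusted p = 6.73e-09) to SPI1 (log2 fold change 1.33, SE 0.06, adjusted p = 1.04e-10). CEBPB (log2 fold change 0.83, SE 0.08, adjusted p = 1.63e-07) stayed below the fold threshold. As a list the 6 were called higher on day 6 than on day 1 (limma's camera, adjusted p = 0.000185), with adjusted p = 0.268 with an estimated correlation. Gene counts cannot separate an introduced copy from the cell's own gene, the names of the 6 come from knowledge of the study and not from the labels, and 43.4% of the exon length of CEBPA overlaps an exon on the other strand.

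**Figure D2:**
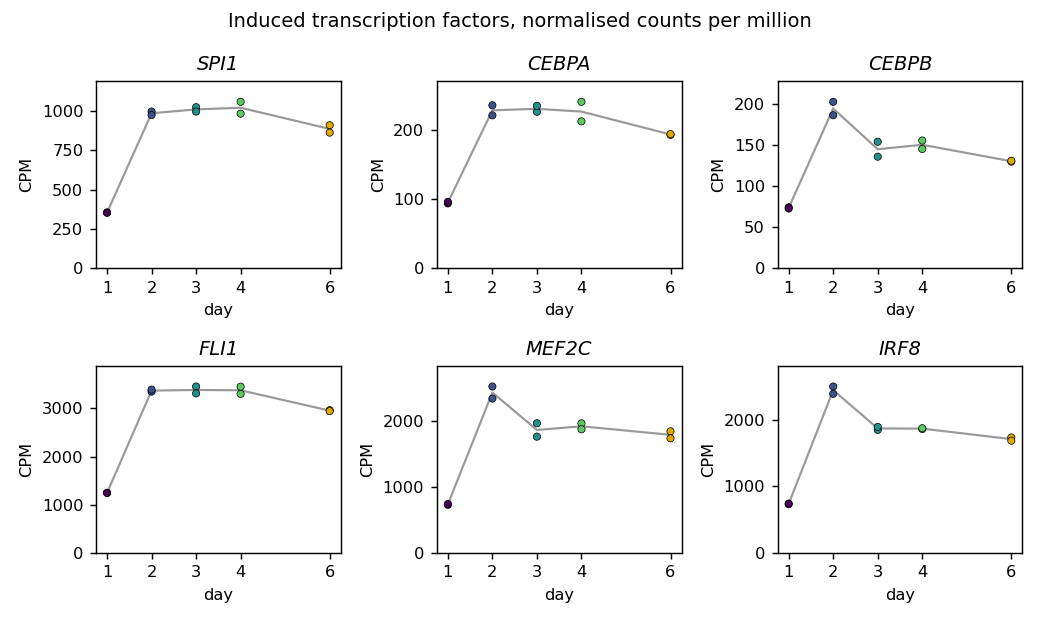
Normalised CPM (y axis) against day of doxycycline (x axis) for the 6 induced transcription factors, with each point a library and the line through the mean of n = 2. Each factor was higher on day 2 than on day 1.

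The main comparison, day 6 against day 1, asked how far expression had moved over the course. Several genes of phagocytes and innate immunity came up from low levels: P2RY13, a purinergic receptor of microglia, rose from 0.253 ± 0.0359 to 419 ± 27.5 CPM, the complement receptor C3AR1 from 0.308 ± 0.194 to 131 ± 11.5 CPM, and the protease CTSS from 1.098 ± 0.215 to 149 ± 2.62 CPM. Genes of pluripotent and epithelial cells went down: LIN28A fell from 296 ± 3.61 to 10.1 ± 0.816 CPM and CLDN6 from 189 ± 5.84 to 2.15 ± 0.350 CPM. Dividing-cell genes fell with them, the kinase AURKB from 104 ± 4.69 to 2.15 ± 0.218 CPM. In all, 4180 genes were higher and 3682 lower on day 6, together 42.8% of the genes tested (edgeR, Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold change), against 4654 higher and 3228 lower with library totals. In simulated counts for this comparison over 17801 genes, the same test called 43.8% of genes given a 2-fold change, 81.6% of those given 4-fold and 98% of those given 8-fold.

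Among called genes of at least 20 CPM in the higher day, the 12 with the largest rise were led by P2RY13 (ENSG00000181631, chromosome 3, 151326312 to 151329548; log2 fold change 10.66, SE 0.19, counting error 0.48, adjusted p = 2e-14). The platelet chemokine PPBP (ENSG00000163736, chromosome 4, 73987038 to 73988197) followed, from 0.112 to 142 CPM (log2 fold change 10.22, SE 0.25, counting error 0.72, adjusted p = 2.99e-13), and then the neutrophil antigen CD177 from 1.21 to 845 CPM (log2 fold change 9.44, SE 0.14, counting error 0.22, adjusted p = 3.55e-15). FOLR2, CEACAM6, OLFM4, C3AR1, ABCB4, HLA-DQA2, CTSS, CLEC1A and LMOD3 followed with log2 fold changes from 9.13 down to 6.96. FOLR2, CEACAM6 and HLA-DQA2 have close paralogs that reads can be shared with, so their levels are less certain. Of the 12 with the largest fall, ZSCAN10 (ENSG00000130182, chromosome 16, 3088890 to 3099317) went from 33.8 ± 0.712 to 0.117 ± 0.0305 CPM (log2 fold change -8.10, SE 0.44, counting error 0.65, adjusted p = 5.61e-10) and creatine kinase CKB (ENSG00000166165, chromosome 14, 103519659 to 103523111) from 143 ± 6.41 to 1.57 ± 0.266 CPM (log2 fold change -6.51, SE 0.19, adjusted p = 1.15e-12). SLC7A3, CLDN6, COL26A1, NES, PIF1, CRMP1, MTSS1L, FLNA and LAD1 were among the others, with log2 fold changes between -6.48 and -5.61; 64% of the exon length of MTSS1L overlaps an exon on the other strand. FLNA (ENSG00000196924, chromosome X, 154348524 to 154374638) was the most abundant of those named on day 1, from 714 ± 12.9 CPM to 14.1 ± 0.914 CPM.

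Genes of the pluripotent state were lower on day 6. POU5F1 (ENSG00000204531, chromosome 6, 31164337 to 31180731) fell from 380.2 ± 10.6 to 114 ± 4.88 CPM (log2 fold change -1.74, SE 0.07, adjusted p = 1.9e-11) and was still expressed on day 6. The telomerase gene TERT fell from 16.3 ± 3.01 to 0.117 ± 0.0305 CPM and PRDM14 from 17.6 ± 0.964 to 0.653 ± 0.118 CPM. SOX2 was low on day 1 at 5.99 ± 0.369 CPM and fell to 1.45 ± 0.164 CPM (log2 fold change -2.04, SE 0.30, adjusted p = 2.48e-05). NANOG was at 1.04 ± 0.135 CPM on day 1 and 0.753 ± 0.413 CPM on day 6 and was not called (log2 fold change -0.47, SE 0.45, adjusted p = 0.357); the change was 0.009 on the log2 scale without day 6 replicate 2. POU5F1 and NANOG have processed pseudogenes that reads can be shared with. Of 22 pluripotency genes tested, 0 were higher, 17 lower and 5 neither over all genes, and 18 were lower adjusted over the list alone. The median log2 fold change was -2.34 (camera, adjusted p = 4.95e-07; adjusted p = 0.301 with an estimated correlation). Of 19 epithelial genes, 1 was higher, 11 lower and 7 neither, and the same counts held adjusted over the list alone. CDH1 fell from 77.8 ± 0.825 to 2.66 ± 0.802 CPM and KRT18 from 224 ± 1.57 to 15.9 ± 0.414 CPM, while PKP2, named after its value was seen, rose from 36.9 to 214 CPM. The epithelial median was -2.38 (camera, adjusted p = 8.16e-05; adjusted p = 0.467 with an estimated correlation).

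Genes of leukocytes, microglia and innate defence were higher. The lipopolysaccharide receptor CD14 rose from 1.21 ± 0.0214 to 85.2 ± 0.177 CPM (log2 fold change 6.13, SE 0.14, counting error 0.22, adjusted p = 1.56e-13), FCER1G from 0.647 ± 0.0496 to 62.0 ± 0.0995 CPM and FCGR2A from 0.563 ± 0.0880 to 29.9 ± 3.58 CPM. Of 37 leukocyte and myeloid genes tested, 27 were higher, 4 lower and 6 neither (median 1.95, adjusted p = 1.37e-05; adjusted p = 0.223 with an estimated correlation). The 4 lower, named after their values were seen, were CD33 (-1.89), LCP1 (-1.89), MSR1 (-1.83) and VAV1 (-1.21). Of 25 homeostatic microglia genes, 17 were higher, 1 (SALL1) lower and 7 neither (median 2.12, adjusted p = 5.84e-05; adjusted p = 0.301 with an estimated correlation). Complement genes included C3, from 4.75 ± 0.350 to 237 ± 9.34 CPM (log2 fold change 5.64, SE 0.16, adjusted p = 8.58e-13), and C1QA, from 1 read in both day 1 libraries to 336 in those of day 6. Of 15 complement genes, 12 were higher, 0 lower and 3 neither (median 1.95, adjusted p = 0.00017; adjusted p = 0.128 with an estimated correlation). In the phagocyte oxidase, CYBB rose from 135 ± 2.81 to 758 ± 58.7 CPM, with 5 of 7 genes higher, 0 lower and 2 neither (median 1.75, adjusted p = 0.0357; adjusted p = 0.467 with an estimated correlation). Of 21 genes of Toll-like and innate sensing, 14 were higher, 1 lower and 6 neither (median 1.59, adjusted p = 0.00124; adjusted p = 0.198 with an estimated correlation). Among them CLEC5A rose from 0.756 ± 0.346 to 54.9 ± 7.10 CPM and TLR1 from 0.167 ± 0.156 to 21.2 ± 0.728 CPM, TLR8 had 0 reads on day 1 and 196 on day 6, and IRAK1, named after its value was seen, was lower (-1.21). For all 5 lists the counts adjusted over the list alone were the same as those over all genes.

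Interferon, lysosome and granulocyte genes were higher as well. The interferon-induced OAS1 rose from 0.114 ± 0.161 to 5.36 ± 0.150 CPM and XAF1 went from 2 reads on day 1 to 737 on day 6. Of 37 interferon response genes, 24 were higher, 0 lower and 13 neither, with the same counts adjusted over the list alone (median 1.86, adjusted p = 5.64e-06; adjusted p = 0.128 with an estimated correlation). Lysosomal ASAH1 rose from 92.7 ± 3.44 to 1321 ± 11.7 CPM (log2 fold change 3.83, SE 0.06, adjusted p = 1.14e-14) and CTSB from 114 ± 2.26 to 729 ± 21 CPM. Of 39 lysosomal genes, 16 were higher, 1 lower (CTSC, named after its value was seen) and 22 neither, with the same counts adjusted over the list alone (median 0.90, adjusted p = 1.64e-05; adjusted p = 0.301 with an estimated correlation). The granulocyte peptide CAMP rose from 3.38 ± 0.369 to 408 ± 41 CPM (log2 fold change 6.91, SE 0.24, adjusted p = 4.8e-12), whereas MMP9 went from 325 reads on day 1 to 3 on day 6. Of 19 granulocyte genes, 11 were higher, 3 lower and 5 neither, with the same counts adjusted over the list alone (median 1.55, adjusted p = 0.0116; adjusted p = 0.467 with an estimated correlation).

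Genes of the cell cycle and of ribosomes were lower. Among replication genes MCM2 fell from 249 ± 9.52 to 14.6 ± 1.37 CPM (log2 fold change -4.10, SE 0.09, adjusted p = 1.01e-13) and RRM2 from 214 ± 0.793 to 15.6 ± 0.175 CPM, and among mitotic genes CDC20 fell from 247 ± 3.91 to 6.90 ± 0.279 CPM and PLK1 from 233 ± 2.35 to 8.37 ± 2.10 CPM. Of 33 replication genes, 0 were higher, 32 lower and 1 neither (median -2.89, adjusted p = 1.24e-16; adjusted p = 0.102 with an estimated correlation). Of 30 mitosis genes, 0 were higher, 30 lower and 0 neither (median -3.20, adjusted p = 8.78e-18; adjusted p = 0.198 with an estimated correlation). Ribosomal RPS3 fell from 1766 ± 8.51 to 489 ± 52.8 CPM and RPL6 from 737 ± 0.631 to 236 ± 10.2 CPM. Of 57 cytosolic ribosomal protein genes, whose many pseudogenes can share reads, 0 were higher, 23 lower and 34 neither (median -0.92, adjusted p = 2.87e-15; adjusted p = 0.467 with an estimated correlation). Of 22 cholesterol synthesis genes, 1 was higher, 3 lower and 18 neither, with SC5D rising from 107 to 341 CPM and FDPS falling from 425 to 186 CPM (median -0.42, adjusted p = 0.018; adjusted p = 0.616 with an estimated correlation). Of 13 mitochondrially encoded mRNAs, 0 were higher, 3 lower and 10 neither, with MT-ND3 falling from 777 to 341 CPM (median -0.60, adjusted p = 0.00338; adjusted p = 0.504 with an estimated correlation). For all 5 lists the counts adjusted over the list alone were the same as those over all genes.

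**Figure D3:**
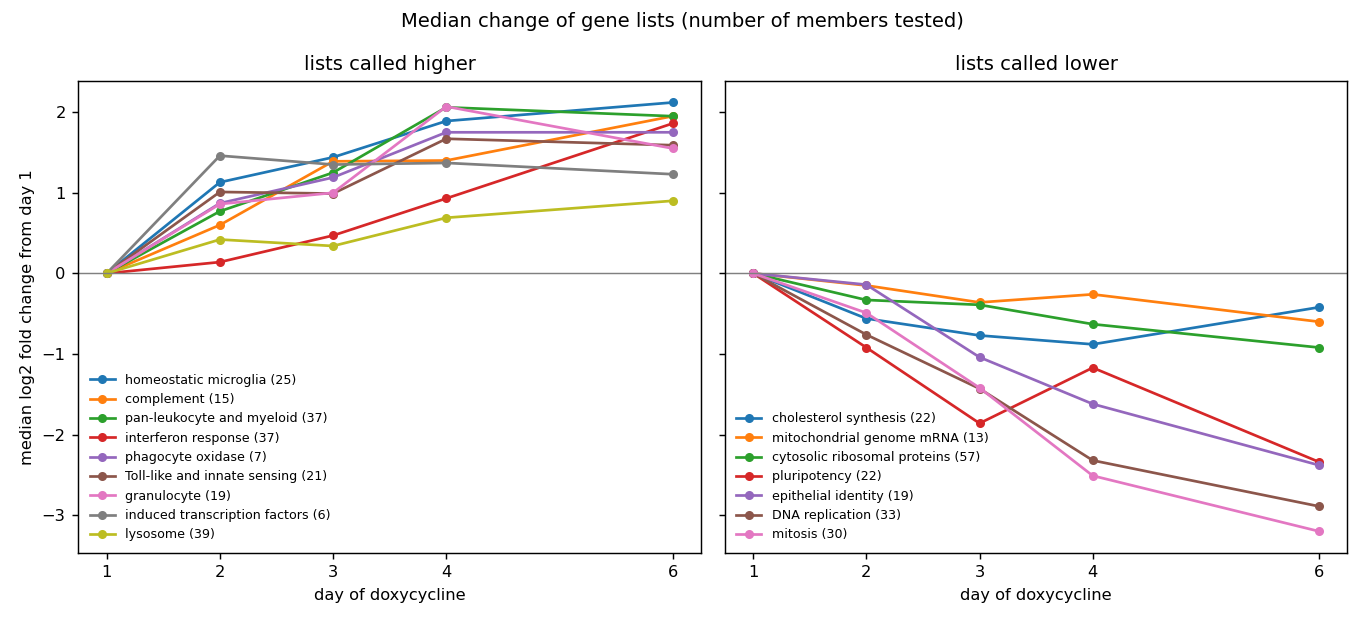
Median log2 fold change from day 1 (y axis) against day of doxycycline (x axis) for the 16 gene lists called by camera between days 6 and 1, with each line a list and the number of tested members in brackets. Medians on day 6 ran from -3.20 for mitosis to 2.12 for homeostatic microglia.

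The other 21 lists were not called by camera. Several held genes that moved strongly both ways. Among endothelial genes KDR rose from 10.7 ± 0.791 to 198 ± 6.37 CPM and PECAM1 from 8.60 ± 0.267 to 129 ± 2.85 CPM, with 7 of 15 higher, 5 lower and 3 neither (adjusted p = 0.515). Disease-associated microglia genes had 7 of 20 higher, 5 lower and 8 neither (adjusted p = 0.262), with SPP1 falling from 22.0 ± 0.0966 to 1.22 ± 0.291 CPM and CLEC7A rising from 0.845 ± 0.251 to 10.6 ± 0.0326 CPM. Mesenchymal genes had 5 of 17 higher, 8 lower and 4 neither (adjusted p = 0.298), among them THY1, which fell from 169.8 to 6.83 CPM. Hematopoietic transcription factors had 8 of 20 higher, 3 lower and 9 neither (adjusted p = 0.164), with HHEX rising from 1.63 to 16.1 CPM and MYB falling from 6.49 to 0.653 CPM. Cytokines and chemokines had 6 of 19 higher, 3 lower and 10 neither (adjusted p = 0.164; called with no filter, median 0.68 and adjusted p = 0.0356), with CXCL10 rising from 5.99 to 38.2 CPM. For antigen presentation by MHC class II 3 of 13 were higher, 1 lower and 9 neither (adjusted p = 0.234): CD74 rose from 61.3 ± 3.76 to 409 ± 16.1 CPM, while HLA-DRA had 52 reads on day 1 and 2 on day 6. For MHC class I 5 of 14 were higher, 2 lower and 7 neither (adjusted p = 0.332), with B2M rising from 132 ± 5.14 to 692 ± 8.14 CPM. Lymphoid genes had 5 of 10 higher, 3 lower and 2 neither (adjusted p = 0.363), with the B-cell factor PAX5 rising from 12.9 ± 0.797 to 107 ± 8.54 CPM.

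Among lists of other lineages and of metabolism, neural genes had 1 of 10 higher, 6 lower and 3 neither (median -1.94, adjusted p = 0.0638), led by NES, which fell from 107 ± 3.17 to 1.71 ± 0.0704 CPM; the list was called without both libraries of day 4 (median -2.51, adjusted p = 0.0479), with library totals (median -1.80, adjusted p = 0.0412), with no filter (median -1.38, adjusted p = 0.028) and with fry (adjusted p = 0.000371), and over all settings adjusted p reached 0.467. With a single library left out the neural list was not called, and its median ran from -1.70 without day 6 replicate 2 to -1.28 without day 1 replicate 2. The filter can keep other members of a list in such fits. Oxidative phosphorylation had 1 of 35 higher (NDUFS3), 1 lower (CYC1) and 33 neither, with a median of -0.23 and adjusted p = 0.0773; it was called without day 6 replicate 2 (median -0.30, adjusted p = 0.0231), with no filter (adjusted p = 0.00759) and with fry (adjusted p = 0.00798), and over all settings adjusted p reached 0.751. Glycolysis had 2 of 23 higher, 9 lower and 12 neither (adjusted p = 0.234), with the glucose carrier SLC2A1 falling from 51.6 to 5.40 CPM and the lactate carrier SLC16A3 rising from 27.5 to 244 CPM. Adipocyte and lipid storage genes had 3 of 16 higher, 5 lower and 8 neither (adjusted p = 0.935), with FASN falling from 697 ± 0.949 to 73.9 ± 3.83 CPM; their median was 0.24, their mean -0.03 and limma's fry gave the downward direction, and camera's direction also turned without day 1 replicate 1 (median 0.21), while the median was 0.13 without day 6 replicate 1 and 0.45 without day 1 replicate 2. Cholesterol efflux genes had 2 of 14 higher, 4 lower and 8 neither (adjusted p = 0.725), with PLTP falling from 59.9 to 10.0 CPM. The p53 targets had 4 of 25 higher, 5 lower and 16 neither (adjusted p = 0.345), stress response genes 2 of 23 higher, 5 lower and 16 neither (adjusted p = 0.234) and immediate early genes 3 of 22 higher, 6 lower and 13 neither (adjusted p = 0.727), with DNAJB9 rising from 21.5 to 138 CPM and DUSP4 falling from 8.02 to 0.186 CPM.

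Many genes of the remaining lists were too low to test. Mesoderm and primitive streak genes had 2 of 7 higher, 2 lower and 3 neither (adjusted p = 0.8), with MIXL1 rising from 2.93 ± 0.680 to 12.4 ± 0.568 CPM; the median was -0.26 although camera gave the upward direction, and with a single library left out it ran from -0.39 without day 6 replicate 1 to 0.71 without day 1 replicate 2. Endoderm genes had 3 of 9 higher, 1 lower and 5 neither (adjusted p = 0.595), with FOXA3 falling from 11.5 to 1.07 CPM. Trophoblast and amnion genes had 2 of 11 higher, 4 lower and 5 neither (adjusted p = 0.658), with SDC1 falling from 11.04 to 0.394 CPM. Erythroid and megakaryocyte genes had 2 of 6 higher, 1 lower and 3 neither (adjusted p = 0.725), with a median of -0.26, a mean of 1.61 and the upward direction in camera; PPBP rose as given above and ITGA2B rose from 1.63 to 4.402 CPM. Of mast cell, basophil and eosinophil genes only CLC and, named after their values were seen, KIT and IL1RL1 could be tested. With 0 higher, 1 lower and 2 neither, CLC alone was lower, from 8.45 ± 0.547 to 3.55 ± 0.451 CPM (median -0.44, mean 0.27, adjusted p = 0.658). With a single library left out the median of this list ran from -0.44 without day 4 replicate 1 to 5.40 without day 1 replicate 2. In such fits the filter can keep other members, so this range and that of the mesoderm list need not come from the libraries alone. For all 21 lists the counts adjusted over the list alone were the same as those over all genes. Limma's fry, which asks whether the genes of a list move to 1 side on balance and compares them with no other genes, called 35 of the 37 lists, and camera with an estimated correlation called 0 (6 lists had an unadjusted p under 0.05), against 16 with the preset correlation.

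Markers of microglia fixed in advance moved in different directions. P2RY12 (ENSG00000169313, chromosome 3, 151337380 to 151384812) rose from 1.47 ± 0.499 to 96.1 ± 13 CPM (log2 fold change 6.03, SE 0.23, adjusted p = 1.24e-11) and CX3CR1 (ENSG00000168329, chromosome 3, 39263494 to 39281735) from 1.27 ± 0.377 to 21.8 ± 0.245 CPM (log2 fold change 4.10, SE 0.29, adjusted p = 1.05e-08). TMEM119 (ENSG00000183160, chromosome 12, 108589846 to 108598320) had 2 reads in both day 1 libraries and 126 in those of day 6, which is 2.95 ± 0.134 CPM. TREM2 rose from 1.66 ± 0.253 to 7.25 ± 0.0262 CPM, AIF1 from 17.4 ± 0.264 to 64.0 ± 4.75 CPM, CSF1R from 13.5 ± 0.272 to 33.5 ± 1.35 CPM and ITGAM from 1.23 ± 0.299 to 61.4 ± 5.77 CPM. SALL1 (ENSG00000103449, chromosome 16, 51135975 to 51151367) fell from 52.4 ± 0.480 to 5.77 ± 0.502 CPM (log2 fold change -3.18, SE 0.14, adjusted p = 7.33e-11). PTPRC, the common leukocyte antigen CD45, had 25 reads over all 10 libraries and was not tested, with mean levels of 0.028 CPM on day 1 and 0.234 CPM on day 6.

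**Figure D4:**
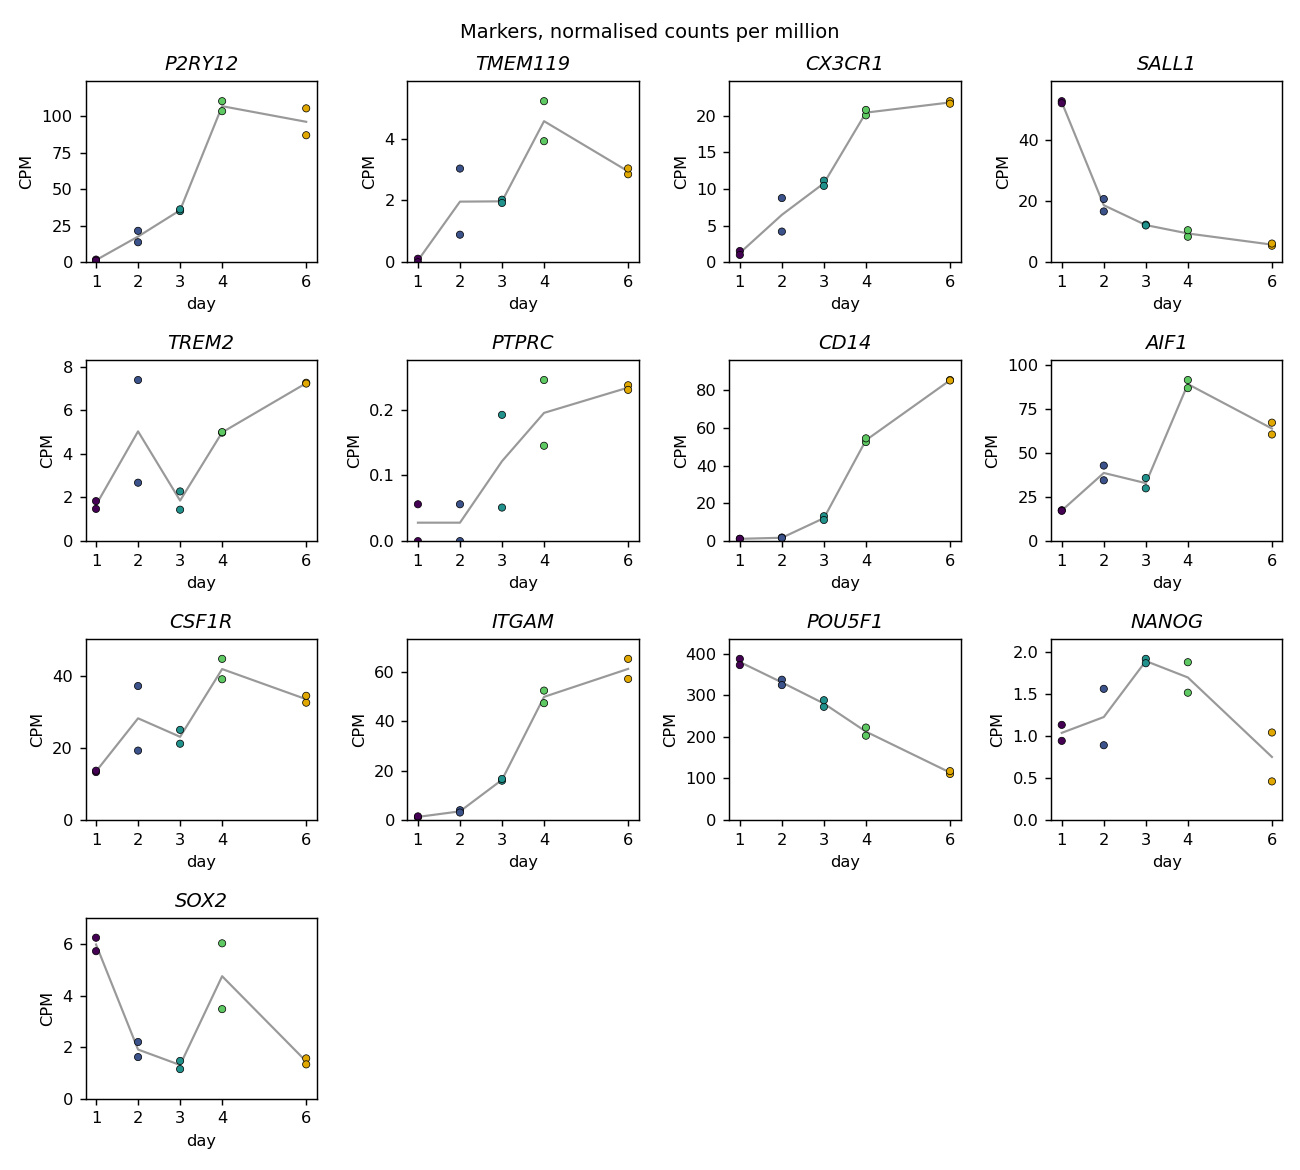
Normalised CPM (y axis) against day of doxycycline (x axis) for markers fixed in advance, with each point a library and the line through the mean of n = 2. P2RY12 and CD14 came up while SALL1 and POU5F1 went down.

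The first step, day 2 against day 1, asked what followed earliest. Of the leukocyte and myeloid genes 15 of 37 were higher and 3 lower. Lysozyme LYZ rose from 89.2 ± 11.2 to 2134 ± 11 CPM (log2 fold change 4.58, SE 0.13, adjusted p = 1.17e-11), OLFM4 from 1.68 ± 0.451 to 95.5 ± 44.9 CPM and the channel AQP9 from 2.42 ± 0.196 to 58.7 ± 6.15 CPM. LMOD3 (ENSG00000163380, chromosome 3, 69106872 to 69123032) had the largest rise among genes of at least 20 CPM, from 0.958 ± 0.332 to 67.5 ± 2 CPM (log2 fold change 6.13, SE 0.18, counting error 0.25, adjusted p = 2.36e-11). The stem cell gene LIN28A fell from 296 ± 3.61 to 25.5 ± 5.64 CPM (log2 fold change -3.53, SE 0.21, adjusted p = 1.16e-08) and CRMP1 (ENSG00000072832, chromosome 4, 5748084 to 5893058) from 29.4 ± 0.0898 to 1.48 ± 0.748 CPM (log2 fold change -4.29, SE 0.36, adjusted p = 3.02e-07). NES, TUBA4A, HPDL and the noncoding AC104257.1 fell as well, with log2 fold changes from -3.90 to -3.20. Of the p53 targets 13 of 25 were higher and 0 lower, and 12 of the 25 were neither: CDKN1A rose from 58.3 ± 6.29 to 234 ± 60.2 CPM and, named after its value was seen, MDM2 from 319.5 ± 6.55 to 685 ± 110 CPM. The median of that list was 1.05 on day 2 and 0.17 on day 6. Interferon response genes split, with 8 of 37 higher, 8 lower and 21 neither, and pluripotency genes had 9 lower and 1 higher. In all 2314 genes were higher and 1352 lower (edgeR), the largest count of any step. An exon on the other strand overlaps 34% of the exon length of LYZ.

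The second step, day 3 against day 2, asked what came next. PPBP rose from 2.00 ± 0.960 to 28.7 ± 1.33 CPM (log2 fold change 3.87, SE 0.18, adjusted p = 1.04e-08), the lipopolysaccharide binding protein LBP (ENSG00000129988, chromosome 20, 38346356 to 38377023) from 3.73 ± 1.12 to 34.7 ± 2.25 CPM (log2 fold change 3.23, SE 0.19, adjusted p = 8.48e-08) and the potassium channel KCNJ15 from 3.98 ± 2.10 to 37.1 ± 2.24 CPM. HLA-DQA2, PCDHB7 and PCDHB8, which have close paralogs, rose with log2 fold changes from 3.22 to 2.86. CKB fell from 25.4 ± 2.92 to 5.11 ± 0.298 CPM (log2 fold change -2.32, SE 0.17, adjusted p = 4.76e-07) and the planar polarity gene VANGL2 (ENSG00000162738, chromosome 1, 160400586 to 160428678) from 39.5 ± 12.5 to 8.25 ± 2.23 CPM. SAPCD2, TUBB2B, LAMP3 and COL1A2 were lower too, with log2 fold changes between -2.20 and -2.01. Of the mitotic genes 15 of 30 were lower, against 3 at the step before, and 0 were higher, while myeloid genes had 13 of 37 higher and 0 lower. The step called 697 genes higher and 832 lower (edgeR), and the count of 1529 was 1149 to 2220 with a single library left out.

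The third step, day 4 against day 3, asked whether the course went on. Among the surface receptors that rose were FOLR2 (ENSG00000165457, chromosome 11, 72216601 to 72221950) from 13.5 ± 1.86 to 117 ± 1.42 CPM (log2 fold change 3.11, SE 0.15, adjusted p = 2.63e-08), C3AR1 from 14.2 ± 2.53 to 74.0 ± 4.39 CPM, IGSF6 from 9.44 ± 1.12 to 53.5 ± 0.00722 CPM and ADGRE3 from 12.7 ± 0.0634 to 57.6 ± 1.43 CPM. CEACAM6 rose from 10.3 ± 0.355 to 71.4 ± 0.185 CPM. Mitotic genes had 22 of 30 lower and 0 higher, with CDC20 falling from 72.8 ± 2.93 to 21.9 ± 1.74 CPM (log2 fold change -1.73, SE 0.16, adjusted p = 4.34e-06). The phospholipase PLCD3 (ENSG00000161714, chromosome 17, 45108967 to 45133354) had the largest fall among genes of at least 20 CPM (log2 fold change -1.85, SE 0.13, adjusted p = 5.37e-07), and LIF, ETV4, KIF22 and CENPW fell by 1.60 to 1.51 on the log2 scale. Of 22 pluripotency genes 6 were higher, 1 lower (LEFTY2, named after its value was seen) and 15 neither, while POU5F1 stood at 280.2 and 213 CPM. Of these genes 3 were higher without day 4 replicate 2, and likewise 3 without day 3 replicate 1 and 3 without day 3 replicate 2, and 0 were lower without day 3 replicate 2, day 4 replicate 1 or day 4 replicate 2. LIN28A rose from 10.9 ± 0.0397 to 34.7 ± 15.8 CPM (log2 fold change 1.67, SE 0.24, adjusted p = 0.000162) and SOX2 from 1.31 ± 0.224 to 4.76 ± 1.81 CPM (log2 fold change 1.86, SE 0.31, adjusted p = 0.000549), and all 6 were higher in day 4 replicate 2 than in replicate 1. The step called 500 genes higher and 405 lower (edgeR), and without day 3 replicate 2 the count of 905 became 600.

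The last step, day 6 against day 4, asked what was still moving. Interferon-induced MX1 rose from 39.1 ± 3.30 to 167 ± 12.4 CPM (log2 fold change 2.09, SE 0.12, adjusted p = 3.95e-07), IFI6 (ENSG00000126709, chromosome 1, 27666061 to 27672218) from 4.09 ± 0.0427 to 24.2 ± 2.81 CPM (log2 fold change 2.57, SE 0.20, adjusted p = 4.79e-06), and IRF7 from 6.67 ± 0.276 to 23.6 ± 4.58 CPM. EPSTI1 rose from 7.72 ± 0.298 to 25.2 ± 0.816 CPM, complement C3 from 70.1 ± 5.43 to 237 ± 9.34 CPM and the leukocyte antigen CD53 from 9.35 ± 0.786 to 44.7 ± 1.17 CPM. Of the interferon response genes 15 of 37 were higher and 0 lower at this step. FLNA fell from 73.6 ± 2.04 to 14.1 ± 0.914 CPM (log2 fold change -2.38, SE 0.08, adjusted p = 5.31e-10), LCN2 from 35.4 ± 9.41 to 9.40 ± 0.00707 CPM and NEBL from 49.0 ± 3.14 to 14.6 ± 2.92 CPM. LIN28A, CDC20 and EPS8L2 were lower too, and 9 of 22 pluripotency genes were lower and 0 higher. Day 2 libraries enter this comparison only through the spread that all days share. The step called 100 genes higher and 266 lower (edgeR), and 529 in all with a fit on days 4 and 6 only. Its count of 366 moved with single libraries: it was 592 without day 2 replicate 1, 595 without day 2 replicate 2, 233 without day 4 replicate 1, 175 without day 4 replicate 2, 150 without day 6 replicate 1, 213 without day 6 replicate 2 and 594 without both libraries of day 2.

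**Figure D5:**
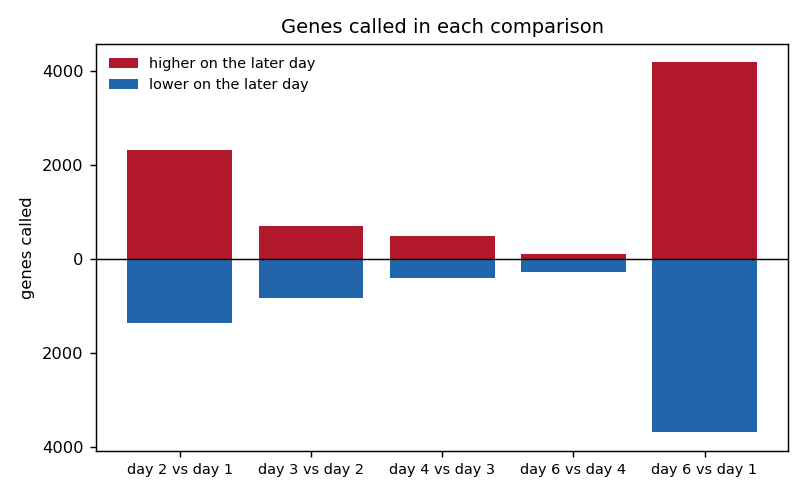
Number of genes called higher (above 0) and lower (below 0) on the y axis for each comparison of days on the x axis. The steps between successive sampled days go from 3666 genes at the first to 366 at the last, day 6 against day 4. With a fit on the compared days only, the 4 steps had 3172, 1088, 1057 and 529 genes.

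Over the whole course 14679 of the 18385 genes changed on some day (edgeR's F test over days, adjusted p under 0.05). Against day 1, 5814 genes were called on day 3, 7379 on day 4 and 7862 on day 6. A smaller group peaked or dipped inside the course. Of these, 429 genes rose on day 2, 3 or 4 and then fell by day 6, and 179 fell and then rose. The lipid transporter ABCA1 stood at 7.14 ± 0.0504 CPM on day 1, 53.3 ± 17.7 on day 2 and 11.1 ± 1.54 on day 6. TCEA3 (ENSG00000204219, chromosome 1, 23381061 to 23424740) went from 3.31 ± 0.188 to 26.3 ± 11.8 and back to 2.64 ± 0.0247 CPM, and LCN2 from 4.55 ± 0.0692 to 50.7 ± 3.59 on day 3 and 9.40 ± 0.00707 CPM on day 6. EPS8L2, NCCRP1 and the noncoding LINC01224 also peaked on day 2. Among the genes that dipped, VAV1 (ENSG00000141968, chromosome 19, 6772714 to 6857366) went from 22.8 ± 1.38 to 2.94 ± 0.133 and then 9.82 ± 0.215 CPM, and the interferon-induced IFIT1 from 28.0 ± 0.687 to 5.84 ± 0.0258 and then 16.6 ± 1.69 CPM. PROM1, IFIT2, GPX8 and the histone gene HIST1H2AC, which has close paralogs, dipped likewise. The libraries of day 2 lay wide apart for the peaks of TCEA3, ABCA1 and EPS8L2, the last with 108 ± 47.8 CPM.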

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

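The alternatives were all set in advance except leaving out both libraries of day 2 or of day 4, and no tests were added for this part. The direction and side of the threshold of most results held: of 212 comparisons of named genes, 212 kept both with RLE scaling, 211 with DESeq2, 211 with limma-voom, 209 with library totals and 207 to 212 with a single library left out. Of the 37 lists, 37 kept both with RLE scaling, 36 with a minimum of 1 CPM and 32 with no filter. Some settings gave no value: a removed day for comparisons with that day, the fit on the compared days for results of the whole course, and the minimum of 1 CPM for the genes and the list it removed. Scaling by library totals moved the median log2 fold change of day 6 against day 1 from 0.04 to 0.18. With the fold threshold dropped, which calls more genes by construction, the counts were 13185 for day 6 against day 1 (6694 higher, 6491 lower), 9931 for day 2 against day 1, 5778 for day 3 against day 2, 5072 for day 4 against day 3, 2047 for day 6 against day 4, 1536 for transient rises and 1206 for transient falls. Testing against a 2-fold change, a stricter null by construction, left 1425, 165, 60 and 20 genes at the 4 steps in order of time, and 69 transient rises and 27 transient falls. DESeq2 gave 277 transient rises, and the cause was not tested. Without both libraries of day 2, which removes a day of the course, 247 transient rises and 102 transient falls were left, and day 6 against day 4 had 594 genes. Camera with an estimated correlation called 0 lists (6 at an unadjusted p under 0.05) and fry, which compares a list with no other genes, called 35.

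With a single library left out, the lone library of that day being assumed to vary like the others, counts ran from 600 to 1112 for day 4 against day 3, 150 to 595 for day 6 against day 4, 3156 to 4132 for day 2 against day 1, 1149 to 2220 for day 3 against day 2 and 7468 to 8311 for day 6 against day 1. NANOG ran from -1.17 to 0.01 (0.009 without day 6 replicate 2). The direction of 3 lists turned, and the cause was not tested: adipocyte genes had a median of 0.24 with fry, 0.38 with library totals and 0.13 to 0.45 with a library left out, mast cell genes 0 with no filter and -0.44 to 5.40 with a library left out, and mesoderm genes -0.42 with no filter and -0.39 to 0.71 with a library left out. The median of neural genes, -1.94 with all libraries, was -1.70 to -1.28 with a library left out. Medians of other lists changed sign too. That of endothelial genes, 0.76 with all libraries, was -0.008 to 0.463 with a library left out. Leaving out a library also changes the low-count filter, whose default rule depends on the smallest group. The members tested can then differ: 22 pluripotency genes were tested with all libraries and 23 without day 1 replicate 1. These ranges thus hold a change of members as well as of libraries, and the parts were not separated. Over all settings erythroid and megakaryocyte genes ran from -0.26 to 0.54 and immediate early genes from -0.30 to 0.04.

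A replicate block for the numbers the libraries carry gave 7815 genes for day 6 against day 1, 3618, 1503, 890 and 363 at the 4 steps and 16 lists, and changed no call of a named gene. Deviations of libraries with the same number correlated at -0.043 to 0.18 over 10 pairs of days and 8336 genes. The correlation passed 0.1 for days 2 and 3 (0.11), 3 and 4 (0.107), 2 and 6 (0.18) and 3 and 6 (0.176) and not for the other 6 pairs, so the libraries were not treated as pairs, and a batch shared within a number on some days stays open. Depth limits the lowest genes: 36521 genes were tested with no filter, 18385 with the default filter and 16044 with a minimum of 1 CPM in 2 libraries.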

Other observations

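The gene families and all tests below were chosen after the results were seen. The Spearman tests of gene length and GC content on the day 2 libraries were set before their own outcomes were seen. Their focus on day 2, however, rests on the spread between libraries in these data. Gene families, some of which share members with the lists, were counted between day 1 and day 6. Protocadherin beta genes, a cluster of cell adhesion genes with close paralogs, had 10 of 13 higher and 1 lower (median 2.31), with PCDHB5 alone lower at -2.42. The 4 lectins tested that carry a SIGLEC symbol, which also have close paralogs, were higher (median 4.25) while CD33 of the same kind was lower at -1.89, and higher too were 9 of 12 C-type lectins (median 2.46), among them CLEC1A at 7.02, CLEC5A at 6.17 and CLEC4E at 2.03. Of 8 annexins 4 were higher and 0 lower (median 0.93), with ANXA4 at 2.08 and ANXA2 at 1.93.

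Tubulins had 8 of 14 lower and 0 higher (median -1.22). Collagens had 20 of 37 lower and 9 higher (median -1.13), and chaperonin subunits 4 of 8 lower and 1 higher. Histone genes of the HIST clusters had 15 of 25 higher and 7 lower (median 1.86), in poly(A) RNA. Amino acid carriers of solute carrier family 7 had 4 of 10 lower and 1 higher (median -0.17), with SLC7A3 at -6.48. No median changed sign with RLE scaling or with library totals, where they ran from -1.08 for tubulins to 4.38 for lectins with a SIGLEC symbol.

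The pluripotency genes SOX2, LIN28A, TDGF1, ZSCAN10, NODAL and ESRG were higher on day 4 than on day 3 and lower again on day 6, and they are taken apart here in groups, with tests and bounds that were revised repeatedly after outcomes were seen. A single day 4 library was excluded as the source for SOX2, LIN28A and TDGF1, whose smallest log2 ratio of the lower day 4 library to day 3 was 1.11, and which stayed called without day 4 replicate 2. For ESRG the ratio of 0.39 in replicate 1 against 2.27 in replicate 2 is in line with a rise in replicate 2 alone (adjusted p = 0.434 without that library), and for ZSCAN10 and NODAL, with 23 and 6 reads on day 3, a smallest ratio of 0.92 leaves a single library (adjusted p = 0.336 and 0.459 without day 4 replicate 2) and a rise in both so that they cannot be told apart. Admixed cells were tested by the share of day 1 expression that a member needs in a day 4 library, less 2 counting errors. For SOX2 and TDGF1 at least 105 of 2562 genes of at least 100 CPM on day 1 lay below it in either library. This excludes cells with the expression of day 1 as the whole source of the rise for both, and for ESRG in replicate 2 with 533 genes below (0 in replicate 1). A smaller share of such cells was not excluded. For LIN28A, NODAL and ZSCAN10 at most 2 genes lay below in the library with fewer, too few to decide. In replicate 2, however, 458 lay below for NODAL, 11 for LIN28A and 1 for ZSCAN10. By the rule used for ESRG, cells with the expression of day 1 would be excluded as the whole source for NODAL and LIN28A in replicate 2. Over both libraries, admixed cells and a rise of the genes themselves cannot be told apart for LIN28A, NODAL and ZSCAN10. All 6 were higher in day 4 replicate 2 than in replicate 1, as were 50.4% of 1147 other genes lower on day 6 than on day 3. Mixing day 1 expression into replicate 1, in the share needed less 2 counting errors, put many of these genes above the measured replicate 2. The percent was at least 81.4% for SOX2, TDGF1, NODAL and ESRG, 74.3% for LIN28A and 55.2% for ZSCAN10. Other days strayed from 50% by up to 9.8. More cells with the expression of day 1 in replicate 2 are thus excluded as the whole source of the difference between the day 4 libraries for all but ZSCAN10. A smaller excess of such cells in replicate 2 was not excluded. For ZSCAN10 this and another cause cannot be told apart. Day 1 cells had already had 1 day of the drug, and day 0 was not analysed here. Cells with a higher level of these 6 genes than on day 1 would need a smaller share, so neither test excludes them. The rise was not confined to the list. AC104257.1, TUBB2B and CRMP1, named above for early falls, were called higher on day 4 than on day 3 (1.97, 1.28 and 1.62) and lower on day 6 than on day 4. AC104257.1 had 10.2 ± 6.37 CPM on day 4. CKB, TUBA4A and HPDL, also named for early falls, were not called on day 4 against day 3. Other genes that fell early were not counted.

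The day 2 libraries lay further apart than those of any other day, with a root mean square log2 difference of 0.315 against 0.135 to 0.15. Of the squared distance, 0.68% lay along the straight line from day 1 to day 3. The course bent at day 2, however. Component 2 was -33.8 and -33.6 on day 1, 53.4 and 41.6 on day 2, and 25.5 and 25.2 on day 3. A shift along a bent course need not follow that line, so a different time point was not excluded. The log2 ratio of the libraries had a Spearman rho across genes of 0.095 (SE 0.0095) with gene length, against 0.288 on day 3 and 0.23 on day 6, and a linear trend over length, a test added after the first outcomes, 0.72 times the largest of another day, which excludes length as what set day 2 apart. With GC content rho was 0.252, against 0.091 at most on other days, and from these values alone a bias tied to GC content and a change in the cells cannot be told apart. With both trends removed, a step chosen after the first outcomes, the difference was 0.301, so gene length and GC content were not the whole cause, and what else set the libraries apart stays open.

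Some leukocyte, microglia and complement genes had hardly any reads although others of their lists rose: 15 members were not tested, among them PTPRC with 25 reads over all libraries, TYROBP with 5 and C1QB with 2. For 11 of them, exons overlap those of no other gene on the same strand in the annotation that gave gene positions here. With that annotation, reads dropped at such overlaps are excluded as the explanation for these 11. The annotation used for counting is not given, so with another annotation such a loss was not excluded. For 2, C2 with 33.3% of its exon length overlapped and CFB with 45.5%, loss of reads at such overlaps and absence of the transcript cannot be told apart. Of protein-coding genes with 25% to 50% overlap 58.0% had 100 reads, against 70.4% of those with none. Loss of reads through overlap on the other strand or through paralogs was not tested. Whether the other genes were silent or are missed by the counting stays open.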
